A study of Curtobacterium with 81 samples.

How the data were processed

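The data comprised 81 RNA libraries from 9 Curtobacterium strains of 3 clades, taken at days 0, 1 and 32 of drying on glass slides with 3 replicates each. Total RNA was treated with DNase and made into libraries with the Kapa RNA Hyper Prep kit, and each sample carried more than 1 set of paired-end reads as technical replicates that may be combined, per the labels' protocols. The submitters' processing notes name Trimmomatic, Bowtie2, Salmon and DESeq, without versions. The reference genomes and the order of the steps are not given in the sources used here. The authors deposited a Salmon quantification per library with estimated counts of reads per locus, which need not be whole, and with effective lengths and abundances that are not used for the tests. The authors also deposited a table of comparisons per strain against day 0, with the mean normalised signal, the log2 fold change and its standard error, and the p-value and adjusted p-value per named gene.

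The quantifications carry locus identifiers and the deposited table carries gene symbols, and no file joins them. The mean normalised signal of each row of the deposited table was therefore recomputed from the estimated counts with size factors and length offsets and matched to loci within a relative tolerance of 1e-06. Of 14146 rows above 0 among 14406, 13969 were matched and 13483 paired with a single locus. After a shift of all values by 1% 21 rows matched, and all 2696 neighbouring rows numbered as copies of one name fell in locus order. The match required leaving out 3 libraries (MMLR14_002 day 0 replicate 2, Wood_21 day 0 replicate 1 and Wood_21 day 32 replicate 3), which the deposited table does not use. For Wood_21 the starting values of this fit were set by hand, since the usual start gave none. Gene names thus rest on this match by value. In Salt_16 and Desert_40 no locus was paired with ssrA, and the most abundant locus of the same length was taken in its place. No reference genome was used, so positions are not given, and reads shared between near-identical copies cannot be told apart; names ending in a number set off by _ are copies of one annotation.

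Estimated counts were rounded to whole numbers. The ssrA transcript and loci under 100 bp were left out of library sizes and tests. Each strain was fitted apart on its 9 libraries with edgeR 4.0.16 in R 4.3.3 (TMM scaling, filterByExpr by day, quasi-likelihood F test), for day 1 and day 32 against day 0 and day 32 against day 1, with Benjamini-Hochberg adjustment over the loci of the strain and a threshold of 0.05. SE of a log2 fold change was derived from the fitted coefficient and its F statistic. Effective lengths were implausibly long in some libraries, up to 1.09e+16, so length offsets were kept for an alternative. For genes measured in all 9 strains the log2 fold changes entered limma 3.58.1 with the strain as the replicate and clade means in the model, for a common change and for a difference between clades. Strain by time interaction was tested with edgeR over the 81 libraries. For 30 gene lists the list median minus the median of all tested loci was tested over strains with an exact two-sided sign-flip test and between clades with an exact permutation over 280 partitions, for lists with at least 3 members in at least 6 strains, adjusted over all lists and comparisons. The toxin-antitoxin list had too few members to be tested. Shares of variance used log2 CPM with a prior count of 1. Where every library of a group had 0 reads, folds were set against a floor of 3 counts over the group, and each bound was computed again without each library, with the scaling unchanged. DESeq2 1.42.0 was run as an alternative. Tables were handled with Python 3.11.15, numpy 2.4.6 and pandas 2.3.3, and figures drawn with matplotlib 3.10.9.

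The tests, contrasts, gene lists and a first set of alternatives were chosen before the data were examined. That set held RLE size factors, DESeq2, no filter on low counts, the replicate number as a block, structural RNAs kept, libraries under 100000 counts left out, a minimum fold, each replicate left out, each strain left out and list means. Length offsets, the 3 libraries left out of the deposited table, genes measured in at least 6 strains, exact tests per gene, groups at 0 set to their bound, bounds without each library and further fits without single strains were added after the data were seen. The comparisons against day 0 share the day 0 libraries, so no overlap or correlation between them was computed.

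Named genes followed a fixed rule: per comparison up to 12 highest and 12 lowest genes over the strains with a common change and the same sign in 9 of 9 strains, the 6 genes with the smallest adjusted p in the clade test, up to 4 members of each list with the smallest adjusted p, members in every list described, and per strain the 2 highest and 2 lowest genes past the threshold whose 3 libraries did not overlap those of day 0 (chance gives no overlap in 10% of genes). From these sets a selection is printed, and other genes are marked as chosen after their values were seen.

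Depth ranged from 417 to 6211220 reads on loci other than tmRNA. Fits within strains were tested on simulated data for day 32 against day 0, from real means, common dispersions and library sizes. Changes of 8-fold were recovered in 99.0% of cases in Pine_43, 97.1% in Wood_52, 96.0% in Salt_16, 94.6% in Desert_40, 93.6% in Desert_3, 90.3% in Grass_32, 84.9% in Desert_35, 46.9% in MMLR14_002 and 0% in Wood_21. Changes of 4-fold were recovered in 73.9% in Desert_3 and in 5.15% in MMLR14_002. Over 285 simulated genes the test of common change recovered 100 of 100 with 2 false calls, the clade test 60 of 60 with 1 false call and the interaction test 20 of 40 with 0 false calls. These simulations across strains used a fixed spread and large set changes, not the spread between the real strains or replicates. Their counts thus do not tell how much these tests recover in the real data. No pair of replicates held identical values, and the closest pair differed by more than sampling noise (chi-square per degree of freedom of 2.08). At day 32 limma's prior had 989 degrees of freedom against 6 residual ones, so nearly the same spread was used for every gene; it had 13.2 at day 1 and 4.68 at day 32 against day 1.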

Results

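RNA was sequenced from 9 isolates of Curtobacterium, a genus of soil actinobacteria, to compare how related strains respond to drying. The isolates fell into clade I (MMLR14_002, Salt_16 and Wood_21), clade IV (Grass_32, Pine_43 and Wood_52) and clade V (Desert_3, Desert_35 and Desert_40). Cells from mid-log culture were washed in saline, spread on glass slides and kept in a desiccation chamber. Total RNA was taken at days 0, 1 and 32 from 3 replicates per strain and day, which gave 81 libraries. No group was kept moist without medium, so drying cannot be told apart from the loss of medium or from time itself. The labels do not say whether replicates were separate cultures, so p-values within a strain measure the spread between these libraries, which may be technical. Each strain was counted on its own genome, with 3284 to 4407 loci per strain and 33451 loci in all.

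A library held 730 to 12308566 estimated reads, with a median of 800164. The tmRNA, the ssrA transcript that releases stalled ribosomes, took a median of 56.4% of the reads and ranged from 8.01% to 91.3% between libraries. The remaining loci received 417 to 6211220 reads, and 21 libraries had under 100000 reads on the tested loci, 8 of them from Wood_21. The median library had 172427 reads on the remaining loci at day 0, 269481 at day 1 and 900700 at day 32, so the day 0 libraries were the shallowest. The tmRNA share had medians of 56.4%, 66.2% and 54.9% at the same days. Wood_21 had so few reads that 297 of its loci could be tested, and no 8-fold change was recovered in it when changes were simulated at its depth and dispersion.

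After 1 day on the slides, most shared genes that changed were lower, among them genes of ribosomal proteins, respiration and chaperones. Among the 64 genes measured in all 9 strains, 36 changed in common over the strains (limma, adjusted p under 0.05), 30 of them lower and 6 higher, and 17 of the 36 had the same sign in every strain. These 64 genes had to pass the count filter in every strain, Wood_21 with its 297 tested loci included, which favours abundant transcripts. They do not stand for all loci, of which more were higher than lower in most strains, though not in Wood_52. The ribosomal protein genes rpsS at −2.84 log2 (SD 1.82, n = 9 strains), rplN at −2.79 (SD 1.80) and rplB at −2.30 (SD 0.97) were lower in 9 of 9 strains, as were rpsJ at −2.11, rplR at −2.03 and rplD at −1.76. The chaperonin gene groL1 fell to −2.44 (SD 0.99) and dnaK, which encodes the Hsp70 chaperone, to −1.91 (SD 1.504). The cytochrome c oxidase gene ctaE stood at −2.17 (SD 1.21), the succinate dehydrogenase gene sdhA at −1.97 (SD 1.29), the ribosome recycling factor frr at −1.92 (SD 1.39) and the regulator pdtaR at −2.03 (SD 0.72). The genes annotated rmpA, at 2.41 (SD 1.86), and camA, at 2.12 (SD 1.40), rose in 9 of 9 strains. The count of 36 was 22 with replicate 2 of every group left out and 62 with replicate 3 left out.

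For the gene lists fixed beforehand, each list's median change at day 1 was set against the median of all tested loci of the strain. Of 29 lists tested, 6 were lower by the exact two-sided sign-flip test over strains and none was higher. The respiratory chain shifted by −1.06 log2 (SD 0.44), cell division and DNA replication by −0.95 (SD 0.63), nucleotide synthesis by −0.73 (SD 0.52) and cell wall synthesis by −0.60 (SD 0.42), each lower in 9 of 9 strains (exact p = 0.00391, the smallest the test can give, adjusted p = 0.0378). Translation factors shifted by −1.203 (SD 1.04) and chaperones and proteases by −1.04 (SD 0.85), each higher in 1 of 9 strains (exact sign-flip test, adjusted p = 0.0485). The ribosomal protein list stood at −1.35 (SD 1.08), was higher in 2 of 9 strains and missed the threshold (exact sign-flip test, adjusted p = 0.0755). ATP synthase at −1.36 (SD 1.25, adjusted p = 0.0637) and aminoacyl-tRNA synthetases at −0.90 (SD 0.77, n = 8, adjusted p = 0.0755) also missed it in the exact test. Cold shock proteins and RNA helicases at 0.83 (SD 0.95, n = 8, adjusted p = 0.113), trehalose synthesis at 0.54 (SD 1.11, n = 8, adjusted p = 0.431) and compatible solutes and osmotic transport at 0.49 (SD 0.69, n = 8, adjusted p = 0.211) were the lists with the highest means, and none passed the exact test. With replicate 2 of every group left out 0 lists passed (the respiratory chain at an adjusted p of 0.068 in the exact test), with replicate 1 left out 3 and with replicate 3 left out 8. Without replicate 1 the calls of chaperones (exact test, adjusted p = 0.154), translation factors (0.185), cell wall synthesis (0.0566) and cell division (0.0906) ended, and amino acid synthesis, at −0.68, passed (0.0425). Without replicate 3 those of cell division and nucleotide synthesis ended (adjusted p = 0.051 each in the exact test) while ribosomal proteins, aminoacyl-tRNA synthetases, ATP synthase and glycolysis passed (0.03998 each), and nucleotide synthesis also missed the threshold with length offsets (adjusted p = 0.051). Ribosomal proteins, aminoacyl-tRNA synthetases and glycolysis passed with length offsets (exact test, adjusted p = 0.0425 each), and the last pair by list mean (0.0485 each). Without Wood_21 the calls of translation factors and of chaperones and proteases ended (exact test, adjusted p = 0.0716 each) and glycolysis passed (0.0453). Cell wall synthesis missed the threshold by list mean (exact test, adjusted p = 0.183), and cell division and DNA replication missed it on members with a single copy in every strain (adjusted p = 0.466 in the exact test).

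Within the lists, members were followed in the 564 genes measured in at least 6 strains, a widening chosen after the data were seen, in which 139 genes were lower and 77 higher at day 1 (limma, adjusted p under 0.05). Of 43 ribosomal protein genes 24 fell and 0 rose (26 and 0 when adjusted over the list alone). Among them were rplW at −3.30 (SD 1.31, n = 7), rplV at −3.04 (SD 1.75, n = 8) and rpsC at −2.18 (SD 1.31, n = 8). Of 13 respiratory chain genes 8 fell and 1 rose (8 and 2 adjusted over the list alone). The Rieske protein gene qcrA stood at −2.51 (SD 0.58, n = 7), while menD, of menaquinone synthesis, stood at 1.35 (SD 1.25, n = 8). Of 16 cell division and replication genes 8 fell and 2 rose (8 and 3 adjusted over the list alone). Lowest were sepF at −3.03 (SD 0.85, n = 7), ftsE at −2.34 (SD 1.75, n = 8) and the DNA polymerase gene dnaE1 at −2.06 (SD 0.66, n = 8). Of 29 nucleotide synthesis genes 9 fell and 0 rose under either adjustment. The lower genes included purQ, of purine synthesis, at −2.39 (SD 1.24, n = 8) and purL at −1.67 (SD 0.63, n = 8). Of 14 chaperones and proteases 6 fell and 0 rose, also when adjusted over the list alone. They included groS at −2.66 (SD 1.23, n = 8) and clpP1 at −2.28 (SD 1.21, n = 8). Of 12 translation factors 5 fell (6 adjusted over the list alone), with lepA at −2.04 (SD 0.72, n = 8) and prfB at −1.85 (SD 0.64, n = 8). Of 12 cell wall genes 3 fell and 1 rose (4 and 1 adjusted over the list alone), mtgA standing at −1.71 (SD 1.59, n = 7) and murB at 1.55 (SD 1.09, n = 7).

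Other lists held members that moved in opposite directions at day 1. In trehalose synthesis 2 of 5 genes rose and 1 fell, under either adjustment, and treZ, with 1 strain that had no read in a group, missed the threshold as fitted (limma, adjusted p = 0.131). The maltokinase gene mak stood at 2.54 (SD 1.54, n = 6) and treY, which makes trehalose from glucan chains, at 1.94 (SD 1.28, n = 8). The trehalose 6-phosphate synthase gene otsA stood at −0.91 (SD 1.29, n = 7). In amino acid synthesis 8 of 50 genes fell and 4 rose (4 and 3 adjusted over the list alone). The glutamine synthetase gene glnA at −3.39 (SD 1.26, n = 8) and the lysine pathway gene dapA at −2.33 (SD 1.66, n = 8) were lower in every strain measured. Among stringent response and ribosome hibernation genes, hpf, which encodes the hibernation promoting factor, rose to 1.49 (SD 1.59, n = 9) and obg to 1.71 (SD 1.23, n = 7), and rsfS fell to −1.49 (SD 1.38, n = 8). In DNA repair 4 of 23 genes rose and 1 fell (3 and 1 adjusted over the list alone), with mutY at 2.00 (SD 1.51, n = 7) and sbcD at 1.94 (SD 1.26, n = 7), both higher in every strain measured. In RNA degradation pnp at 1.27 (SD 0.82, n = 9) and rnc at 1.42 (SD 0.99, n = 8) rose, and rnj at −1.63 (SD 0.71, n = 6) fell.

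**Figure D1:**
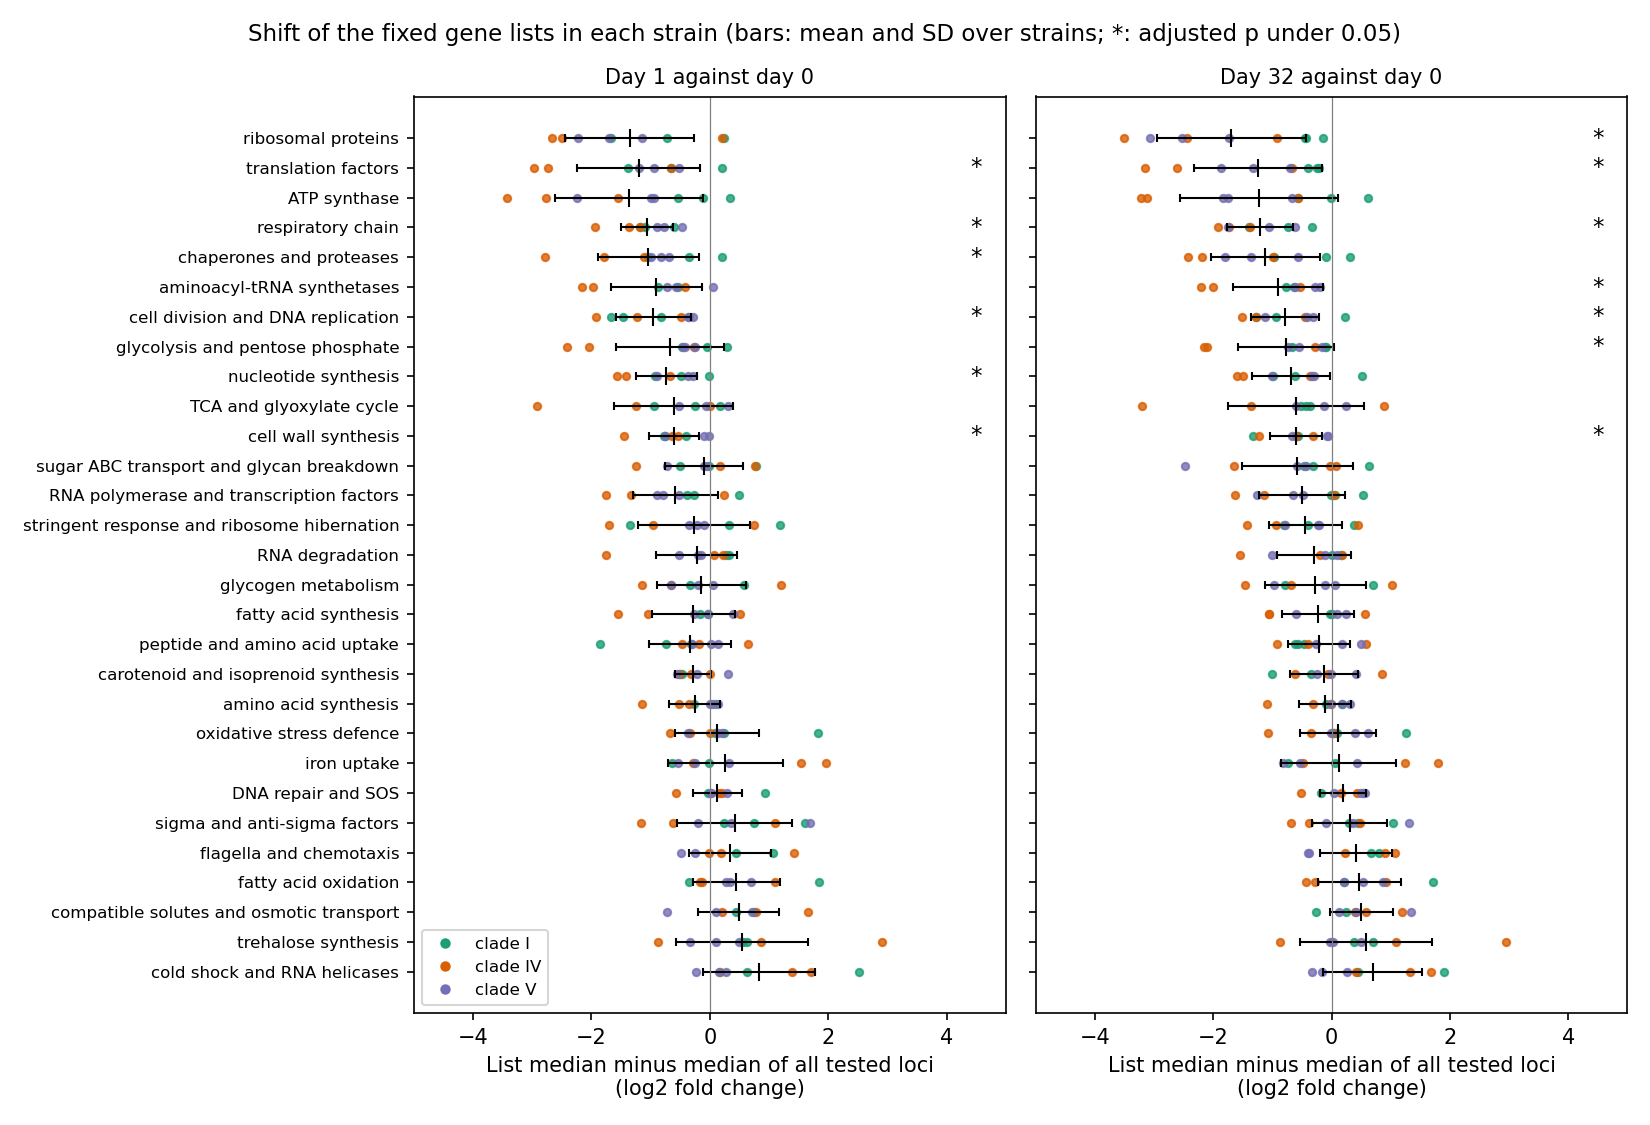
Shift of each fixed gene list, as the list's median log2 fold change minus the median of all tested loci of the strain, at day 1 (left) and day 32 (right) against day 0. Points are strains coloured by clade, bars give the mean and SD over 7 to 9 strains, and stars mark the 6 lists at day 1 and 7 lists at day 32 with an adjusted p under 0.05 in the exact sign-flip test. The mean of the ribosomal protein list was −1.35 at day 1 and −1.69 at day 32, and day 32 set against day 1 gave −0.10 (exact sign-flip test, adjusted p = 0.824, but 0.0425 without replicate 1 of every group).

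The number of loci that changed by day 1 differed widely between strains (edgeR, adjusted p under 0.05). Pine_43 had 1167 loci higher and 648 lower of 3262 tested, Grass_32 1105 higher and 367 lower of 3400, Salt_16 659 and 419 of 2870, and Wood_52 337 and 374 of 1819. Desert_3 had 170 loci higher and 94 lower of 1639, MMLR14_002 73 and 20 of 2183, and Desert_35 67 and 34 of 2912. Wood_21 had 1 locus higher, 49 at an unadjusted p under 0.05 and 15 by DESeq2. In Desert_40 edgeR called 0 of 2300 loci, against 228 at an unadjusted p under 0.05 and 29 by DESeq2. The median log2 fold change of all tested loci was 1.09 in Grass_32, 0.61 in Pine_43 and −0.41 in Wood_52. In the other strains it lay between −0.15 and 0.36. The split into higher and lower loci thus depends on where the scaling sets 0. The ribosomal protein genes rplN and rplV led the decrease in Pine_43, at −5.92 (SE 1.09) and −5.83 (SE 0.92). In Grass_32 the ATP synthase gene atpH_2 stood at −5.92 (SE 0.82) and rpsS at −4.79 (SE 0.57), and in Desert_3 atpH_2 stood at −5.19 (SE 0.72) and rpsN at −4.52 (SE 0.65). In Desert_35 rpsS at −4.78 (SE 0.98) and rplN at −3.75 (SE 0.84) fell and macB_2 rose to 5.18 (SE 1.03), from 15 reads over the day 0 libraries. In MMLR14_002 the sigma factor gene sigK_2 rose to 6.53 (SE 1.15) and rnpA, the protein part of RNase P, to 4.92 (SE 1.00), while ccs1 fell to −4.47 (SE 0.98), with 9 reads over the day 1 libraries. With the MMLR14_002 libraries under 100000 counts left out, sigK_2 had an edgeR adjusted p of 0.121, rnpA of 0.087 and ccs1 of 0.0765. The call of ccs1 also ended without day 1 replicate 1 or 2 (edgeR, adjusted p = 0.0525 and 0.084). In Desert_35 the calls of rpsS and rplN ended without day 1 replicate 3 (edgeR, adjusted p = 0.0583 each), and that of macB_2 without day 0 replicate 1 or 2 (adjusted p = 0.0512 and 0.146). With length offsets all 3 calls ended (edgeR, adjusted p = 0.104 for rpsS, 0.105 for rplN and 0.0794 for macB_2). In Salt_16 appA at −5.06 (SE 0.81) and the phosphoserine phosphatase gene serB2 at −4.50 (SE 0.63) fell, with 11 and 75 reads over the day 1 libraries. In Wood_52 lnt, which encodes an apolipoprotein acyltransferase, rose to 7.13 (SE 0.67).

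Several genes had no read in all 3 day 0 libraries, and their folds are lower bounds against a floor of 3 counts over the group, which covers counting error alone. The gene lacC_1 reached 131 CPM (SD 30.1, n = 3) at day 1 in Pine_43, at least 54.8-fold higher, or 23.8-fold without day 0 replicate 2. In Salt_16 tgnD reached 456 CPM (SD 537), at least 121-fold higher, but 516 of its 614 reads at day 1 came from replicate 1. The bound was 38.965-fold without that library, 69.4-fold without day 0 replicate 1 and 76.7-fold without day 0 replicate 2. The arsenical efflux gene arsB reached 119 CPM (SD 11.3) in Grass_32, at least 17.1-fold higher, or 8.33-fold without day 0 replicate 3. In Desert_3 rimM, a ribosome maturation gene, reached 240 CPM (SD 15.6), at least 8.39-fold higher, or 4.39-fold and 4.88-fold without day 0 replicates 1 and 2. In Wood_52 tatB, of the twin-arginine transport system, had 235 reads at day 0 and 0 at day 1, at least 10.5-fold lower, or 3.30-fold without day 1 replicate 3. There betB_1, annotated as betaine aldehyde dehydrogenase, had 0 reads at day 0 and 21 at day 1 (40.3 CPM, SD 36.8), 19 of them in replicate 3. It was at least 31.2-fold higher, or 14.7-fold without that library and 12.8-fold without day 0 replicate 1.

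The counts in several strains rested on single libraries. At day 1, MMLR14_002 went from 93 changed loci to 2 with libraries under 100000 counts left out, and to 31 without day 0 replicate 2, 33 without day 1 replicate 1 and 40 without day 1 replicate 2. Desert_35 went from 101 to 6 without day 0 replicate 2, to 13 without day 0 replicate 1 or day 1 replicate 3 and to 63 without day 0 replicate 3. It went to 62 and 51 without day 32 replicates 2 and 3, but to 157 without day 1 replicate 1 and 179 without day 32 replicate 1. Desert_3 went from 264 to 113 and 151 without day 0 replicates 2 and 1, to 165 without day 1 replicate 3 and to 423 without day 1 replicate 2. Salt_16 went from 1078 to 665 without day 0 replicate 2, Wood_52 from 711 to 358 without day 1 replicate 3, and Grass_32 from 1472 to 930 and 963 without day 0 replicates 1 and 2. Wood_21 went from 1 to 59 and 22 without day 32 replicates 1 and 2 and to 0 without any of its other libraries except day 32 replicate 3. Desert_40 went from 0 to 13 without day 1 replicate 1. Scaling moved the balance in a pair of strains: with RLE size factors Desert_35 had 212 loci higher and 25 lower (DESeq2, 252 and 32) and MMLR14_002 had 73 higher and 5 lower. RLE size factors moved the median log2 fold change of all loci at day 1 by 0.56 in Desert_35, 0.43 in Wood_21, 0.16 in Desert_3, −0.13 in Salt_16 and −0.26 in Wood_52. At day 32 it moved by 0.91 in Desert_35, 0.20 in Desert_3, −0.15 in both Pine_43 and Desert_40, −0.16 in Wood_52 and −0.24 in Salt_16.

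**Figure D2:**
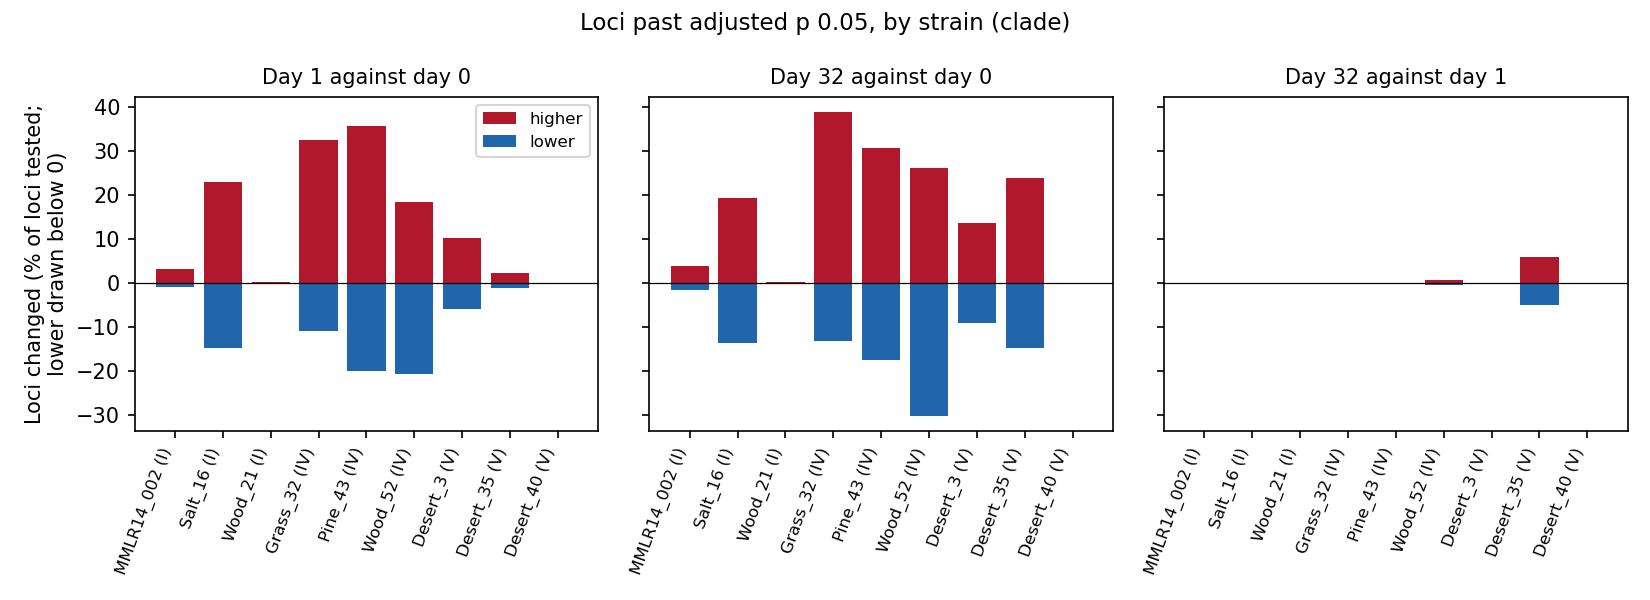
Loci past an adjusted p of 0.05 in edgeR, as a percentage of the loci tested in each strain (clade in brackets), with higher loci drawn above 0 and lower loci below, for each pair of days. At day 32 against day 0 the total ran from 0.130% of loci in Desert_40 to 56.3% in Wood_52; at day 32 against day 1 Wood_52 (1.04%) and Desert_35 (10.9%) had changed loci and the other 7 strains had 0.

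After 32 days in the desiccation chamber, transcripts for ribosomal proteins, translation factors, the respiratory chain, and glycolysis and the pentose phosphate pathway were lower relative to the median of all loci. Of the 64 genes measured in all 9 strains, 39 changed in common (limma, adjusted p under 0.05), 33 lower and 6 higher, with the same sign in every strain for 8 of them. That this count was below the 17 of day 1 rests in part on Wood_21, the shallowest strain. Wood_21 alone was higher in rpsS (0.11), rpsJ (0.72), ctaE (0.26), rplB (0.42), dnaK (0.83) and groL1 (1.81), among others. In rpmI Desert_3 (0.17) and in rplF Wood_52 (0.18) alone was higher. The ribosomal protein genes rplN, at −3.13 (SD 1.73, n = 9), and rplK, at −1.37 (SD 1.00), were lower in 9 of 9 strains. The mannitol transporter gene mtlA, at −2.31 (SD 1.12), the glycerol facilitator gene glpF, at −1.66 (SD 0.96), and the acyl carrier protein gene acpP, at −1.23 (SD 0.59), were also lower in 9 of 9. The genes rmpA at 2.40 (SD 1.43), camA at 2.25 (SD 1.40) and fadB, of fatty acid oxidation, at 1.18 (SD 0.77) were higher in 9 of 9. An exact sign-flip test of each gene over strains, added after the data were seen, called 28 genes at day 32 and 32 at day 1.

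By lists, 7 of 29 were lower at day 32 against the median of all tested loci, and none was higher. That median itself ran from −0.28 in Wood_52 and −0.16 in MMLR14_002 to 0.53 in Pine_43, 0.58 in Wood_21 and 1.17 in Grass_32, with 0.16 to 0.40 in the other 4 strains. Ribosomal proteins shifted by −1.69 (SD 1.25), translation factors by −1.24 (SD 1.08), the respiratory chain by −1.21 (SD 0.56), glycolysis and the pentose phosphate pathway by −0.76 (SD 0.81) and cell wall synthesis by −0.60 (SD 0.44), each lower in 9 of 9 strains (exact sign-flip test, adjusted p = 0.0378). Aminoacyl-tRNA synthetases shifted by −0.90 (SD 0.76, lower in 8 of 8 strains) and cell division and DNA replication by −0.78 (SD 0.57, higher in 1 of 9), with an adjusted p of 0.0485 each in the exact test. Chaperones and proteases at −1.12 (SD 0.92, adjusted p = 0.0637), nucleotide synthesis at −0.69 (SD 0.66, adjusted p = 0.085) and ATP synthase at −1.23 (SD 1.33, adjusted p = 0.108) were higher in 1 of 9 strains each and missed the threshold of the exact test. Cold shock proteins and RNA helicases at 0.69 (SD 0.84, n = 8, adjusted p = 0.201), trehalose synthesis at 0.59 (SD 1.11, n = 8, adjusted p = 0.376) and compatible solutes and osmotic transport at 0.51 (SD 0.54, n = 8, adjusted p = 0.113) had the highest means, and none passed the exact test. With replicate 2 of every group left out 0 lists passed (ribosomal proteins at an adjusted p of 0.0716 in the exact test), and with replicate 1 left out 4. Without replicate 2 ribosomal proteins still stood at −1.65, translation factors at −1.12, the respiratory chain at −1.16 and glycolysis at −0.71. Cell wall synthesis stood at −0.50, aminoacyl-tRNA synthetases at −0.73 and cell division at −0.61. As at day 1, no list could pass alone, so each call also depended on the p-values of the other lists. Without replicate 1 the calls of ribosomal proteins and aminoacyl-tRNA synthetases (exact test, adjusted p = 0.0566 each), translation factors (0.0906) and glycolysis (0.143) ended. Nucleotide synthesis passed without replicate 1 (exact test, adjusted p = 0.0425), without replicate 3 (0.03998), without Wood_21 (0.0453) and on members with a single copy in every strain (0.0352). ATP synthase passed without replicate 3 (exact test, adjusted p = 0.03998), and chaperones and proteases with length offsets (0.0425) and without Wood_21 (0.0453). Cell division and DNA replication missed the threshold on members with a single copy in every strain (exact test, adjusted p = 0.230) and with length offsets (0.051).

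Among the 564 genes measured in at least 6 strains, 155 were lower and 104 higher at day 32. Of 43 ribosomal protein genes 26 fell and 0 rose under either adjustment. These included rplW at −3.89 (SD 1.59, n = 7), rpsS at −3.54 (SD 2.07, n = 9), rplV at −3.09 (SD 1.97, n = 8) and rpmD at −2.94 (SD 2.01, n = 8). Counted in each strain apart, 126 of 362 ribosomal protein loci were lower and 8 higher in edgeR (152 and 7 adjusted over the list alone). Of 12 translation factors 7 fell and 0 rose under either adjustment, with lepA at −2.32 (SD 0.44, n = 8) and prfB at −2.18 (SD 0.77, n = 8). Of 13 respiratory chain genes 8 fell and 2 rose under either adjustment. The gene ctaE stood at −2.33 (SD 1.37, n = 9) and qcrC at −1.89 (SD 1.29, n = 8), while menC at 1.73 (SD 0.80, n = 6) and menD at 1.66 (SD 1.34, n = 8) rose. Of 12 glycolysis and pentose phosphate genes 7 fell and 2 rose under either adjustment. The ribose 5-phosphate isomerase gene rpiB stood at −2.09 (SD 1.12, n = 8), against pgk at 1.25 (SD 0.60, n = 8) and tpiA at 1.45 (SD 1.15, n = 7). Of 18 aminoacyl-tRNA synthetase genes 6 fell and 0 rose (3 and 0 adjusted over the list alone), with metG at −1.57 (SD 0.75, n = 8) and glyQS at −1.59 (SD 0.74, n = 7). In cell division and replication 8 of 16 genes fell and 3 rose under either adjustment. The gene sepF stood at −3.43 (SD 0.83, n = 7) and ftsE at −2.82 (SD 1.17, n = 8), and the ligase gene ligA at 1.53 (SD 1.14, n = 6). In cell wall synthesis 4 of 12 genes fell and 1 rose under either adjustment, with mtgA at −2.06 (SD 1.43, n = 7) and murB at 1.71 (SD 0.90, n = 7).

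In lists that missed the threshold of the exact test, single members rose or fell at day 32. In trehalose synthesis mak at 2.50 (n = 6) and treY at 1.90 (SD 1.25, n = 8) were higher in every strain measured, and otsA stood at −0.84 (SD 1.16, n = 7). Of 23 DNA repair genes 8 rose and 1 fell (6 and 1 adjusted over the list alone). Higher were mutY at 2.14 (SD 1.22, n = 7), sbcD at 1.91 (SD 1.15, n = 7), recN at 1.61 (SD 1.35, n = 7) and the SOS repressor gene lexA at 1.38 (SD 1.26, n = 8). The helicase gene uvrD1 at −1.45 (SD 0.63, n = 8) was lower. The hibernation factor gene hpf stood at 1.49 (SD 1.19, n = 9), glgB, of glycogen synthesis, at 1.26 (SD 1.17, n = 8), and the proline synthesis gene proA at 1.22 (SD 1.05, n = 7). In amino acid synthesis 9 of 50 genes rose and 8 fell (7 and 6 adjusted over the list alone), with glnA at −3.51 (SD 1.63, n = 8) and dapA at −2.10 (SD 1.23, n = 8). The pyruvate dehydrogenase gene aceE at −1.82 (SD 0.97, n = 8) and the citrate synthase gene gltA2 at −2.10 (SD 1.18, n = 7) fell in every strain measured. The superoxide dismutase gene sodA had a mean of −1.12 (SD 1.64, n = 9) and was higher in 4 of 9 strains.

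By strain, edgeR called 1326 loci higher and 444 lower at day 32 in Grass_32, 1001 and 565 in Pine_43, 698 and 426 in Desert_35, 478 and 547 in Wood_52, 555 and 387 in Salt_16, 225 and 147 in Desert_3 and 84 and 31 in MMLR14_002. Desert_40 had 3 loci lower: glnA at −5.18 (SE 0.77), the ammonium transporter gene amtB at −4.05 (SE 0.67) and atpH_2 at −4.05 (SE 0.65), the last named after its value was seen. Wood_21 had 1 locus higher, against 31 at an unadjusted p under 0.05 and 1 lower by DESeq2. The ribosomal protein gene rplM stood at −6.73 (SE 0.89) in Desert_35 and −6.54 (SE 0.75) in Desert_3. It had 3 reads over the day 32 libraries of Desert_35 and 44 over those of Desert_3. The gene rpsS stood at −5.89 (SE 1.04) in Desert_35 and −5.95 (SE 1.47) in Pine_43, and rpmB at −5.18 (SE 0.71) in Desert_3. Reads of rpmB there were 36 over the day 0 libraries and 43 over those of day 32. The ATP synthase gene atpH_2 stood at −7.37 (SE 0.90) in Grass_32, −5.73 (SE 1.14) in Pine_43 and −4.49 (SE 0.86) in Salt_16. In MMLR14_002 sigK_2 at 5.68 (SE 1.11) and cytR_2 at 4.73 (SE 0.98) rose and the oxidase gene ctaD at −3.82 (SE 0.94) fell. The calls of sigK_2 and cytR_2 ended without day 0 replicate 2 (edgeR, adjusted p = 0.0628 and 0.0503). With libraries under 100000 counts left out, sigK_2, cytR_2 and ctaD had edgeR adjusted p-values of 0.175, 0.169 and 0.266. That of ctaD ended without day 0 replicate 1 or 2 (adjusted p = 0.057 and 0.0911) or day 32 replicate 2 or 3 (adjusted p = 0.113 and 0.216). In Wood_52 ccpA rose to 7.56 (SE 0.82), from 3 reads over the day 0 libraries to 383 at day 32. Those 3 reads equal the floor set for groups at 0, so the size of this fold is uncertain. In Salt_16 tagH_2 fell to −4.65 (SE 0.83). Against 0 reads at day 0, betB_1 reached 141 CPM (SD 59.1, n = 3) in Wood_52, at least 109-fold higher, or 44.9-fold without day 0 replicate 1. In Grass_32 menH_2 reached 281 CPM (SD 212), at least 40.4-fold higher, or 19.7-fold without day 0 replicate 3 and 24.3-fold without day 32 replicate 2. In Pine_43 lacC_1 reached 67.3 CPM (SD 12.2), at least 28.2-fold higher, or 12.2-fold without day 0 replicate 2. In Wood_52 the glycine cleavage gene gcvH had 59 reads at day 0 and 0 at day 32, at least 14.2-fold lower, or 7.09-fold without day 32 replicate 3.

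Some of these day 32 counts also depended on a single library or on scaling. Desert_40 went from 3 to 196 loci without day 1 replicate 1 and to 0 without any one of its day 0 or day 32 libraries, and its DESeq2 count was 69. With libraries under 100000 counts left out Desert_40 had 229 changed loci and MMLR14_002 had 1. MMLR14_002 went from 115 to 16 without day 0 replicate 2, 30 without day 32 replicate 3, and 63 and 65 without day 1 replicates 1 and 2. Desert_35 went from 1124 to 487 and 478 without day 0 replicates 1 and 2 and to 601 and 597 without day 32 replicates 2 and 3. Salt_16 went from 942 to 458 and 570 without day 0 replicates 2 and 3 and to 537, 623 and 612 without day 32 replicates 1, 2 and 3. Desert_3 went from 372 to 203 and 247 without day 0 replicates 2 and 1 and to 247 and 222 without day 32 replicates 2 and 3, and Grass_32 from 1770 to 1107 without day 32 replicate 2. Wood_21 went from 1 to 45, 56 and 2 without day 32 replicates 1, 2 and 3, and to 0 without any of the others. With RLE size factors Desert_35 had 1315 loci higher and 247 lower (DESeq2, 1052 and 159), Salt_16 48.9% of its changed loci higher in place of 58.9% (DESeq2, 529 higher and 569 lower) and MMLR14_002 77 higher and 11 lower.

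Between day 1 and day 32, 2 strains had changed loci. Desert_35 had 173 loci higher and 144 lower. The porphyrin synthesis gene hemC at 5.02 (SE 0.85) and the glucokinase gene glcK at 4.82 (SE 1.05) were higher and rplM at −3.57 (SE 1.00) lower, genes chosen after their values were seen. Wood_52 had 14 loci higher and 5 lower, among them ccpA at 2.94 (SE 0.64) and the flagellar export gene flhA at 3.48 (SE 0.79), also chosen after their values were seen. In the other 7 strains edgeR called 0 loci, with 7 at an unadjusted p under 0.05 in MMLR14_002, 49 in Salt_16, 11 in Wood_21, 12 in Grass_32, 101 in Pine_43, 27 in Desert_3 and 92 in Desert_40. DESeq2 called 1 in Desert_40 and 0 in the other 6. Over the strains limma called 0 of the 64 shared genes, with 4 at an unadjusted p under 0.05 and 0 by the exact sign-flip test, and it called 9 without replicate 1 of every group. Of the lists, amino acid synthesis was higher by 0.09 (SD 0.07) in 8 of 8 strains (exact sign-flip test, adjusted p = 0.0485), and the call ended without replicate 1, 2 or 3 of every group (adjusted p = 0.0906, 0.068 and 0.324 in the exact test) and by list mean (adjusted p = 0.188), with length offsets (0.0591) and on members with a single copy in every strain (0.338). Ribosomal proteins, at −0.10 with all libraries, stood at −0.79 without replicate 1 of every group and passed (exact sign-flip test, adjusted p = 0.0425). The nucleotide synthesis list stood at 0.30 (SD 0.57, higher in 8 of 9 strains) and missed the threshold (exact sign-flip test, adjusted p = 0.108).

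Single libraries decided several of the day 32 against day 1 counts. Pine_43 went from 0 to 1205 changed loci without day 1 replicate 3, Salt_16 from 0 to 46 without day 1 replicate 3, Desert_40 from 0 to 59 without day 1 replicate 1, Wood_21 from 0 to 80 without day 32 replicate 2 and Desert_3 from 0 to 1 without day 1 replicate 2. Wood_52 went from 19 to 1 without day 1 replicate 1 or 2 and 6 without day 32 replicate 1, and to 173, 33 and 32 without day 32 replicate 2, day 32 replicate 3 and day 0 replicate 3. Desert_35 went from 317 to 38, 69 and 76 without day 32 replicate 3, day 32 replicate 2 and day 1 replicate 2. It went to 193, 195 and 165 without day 0 replicates 1, 2 and 3 and 183 without day 1 replicate 3, and to 751 and 633 without replicate 1 of day 1 and of day 32. With RLE size factors Desert_35 had 265 loci higher and 69 lower, with DESeq2 62 and 7, and with length offsets 13 and 5, and Wood_52 had 18 and 15 with length offsets.

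The clades were compared for genes whose change differed more between clades than between strains of a clade. At day 32, 14 of the 64 shared genes differed by limma, led by the ribosomal protein genes rplO (clade means 1.86 in I, −1.27 in IV and −2.38 in V, adjusted p = 0.000202) and rpsB (1.76, 0.24 and −2.21, adjusted p = 0.000787), with n = 3 strains per clade. The gene rpsS was lower in every clade, with means of −1.43, −4.58 and −4.62 (limma, adjusted p = 0.00312). Clade IV had the lowest means of dnaK, at −3.84 against −0.68 in I and −1.35 in V (limma, adjusted p = 0.0100), and of the cytochrome gene qcrB, at −3.40 against −0.43 and −1.14 (limma, adjusted p = 0.0175). The methionine sulfoxide reductase gene msrB had means of 2.90 in I, 0.97 in IV and −0.27 in V (limma, adjusted p = 0.0146). None of the 14 passed an exact permutation of strains among clades (smallest adjusted p = 0.168), but the 280 partitions allow no p under 0.00357, at which a gene alone cannot pass the adjustment over 64 genes. limma called 0, 12 and 4 without replicate 1, 2 or 3 of every group, 0 without Wood_21, 4 to 8 without MMLR14_002, Salt_16, Grass_32 or Desert_35, and 41 without Wood_52. It called 22 from DESeq2 fold changes, 23 with RLE size factors, 1 without a filter on low counts, 0 with length offsets and 0 of the 564 genes measured in at least 6 strains. The count thus moved both ways, and the differences were not established. limma called 0 genes at day 1 and at day 32 against day 1, with 13 and 4 at an unadjusted p under 0.05 and 0 by the exact permutation, and DESeq2 fold changes gave 11 at day 1. Of the 16 lists measured in every strain, 0 differed between clades in any of the comparisons (exact permutation, smallest adjusted p = 0.379, with 3, 0 and 1 lists at an unadjusted p under 0.05). A list alone could not have passed, since the smallest p of the exact permutation is 0.00357 before adjustment.

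The response of the strains was also compared gene by gene. Among 285 genes with a single named copy in all 9 genomes, 139 had a strain by time interaction (edgeR, adjusted p under 0.05). Smallest were kdpB, of a potassium transporter (adjusted p = 2.24e-07), mscL, the large mechanosensitive channel (adjusted p = 2.24e-07), rplO (adjusted p = 9.03e-07) and tatB (adjusted p = 1.19e-06). Next came the glycerol kinase gene glpK (adjusted p = 5.31e-05) and the regulator gene whiB1 (adjusted p = 0.000110). These 6 genes were taken by rank after the data were seen. The count was 57, 30 and 59 with replicate 1, 2 or 3 of every group left out. The test measures the spread between libraries, which may be technical. Whether 139 genes exceed what chance gives beside a common response was not settled. Of the variance of log2 CPM over these genes and the 81 libraries, 36.1% (jackknife SE 5.65) lay between strains, 8.05% (SE 3.41) between days, 13.4% (SE 3.01) in the interaction of strain and day and 42.5% (SE 3.98) between replicates. The interaction share was 22.1%, 16.97% and 21.9% with replicate 1, 2 or 3 left out, and the strain share was 42.9% without replicate 2. The shares were not corrected for degrees of freedom, so spread between replicates alone adds to the interaction share, more so with fewer replicates. The interaction share is thus no measure of how far the strains differed in their response.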

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

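The tests on Desert_35, on exchanged libraries, of the clade partitions at day 32, of single genes by exact permutation and with length offsets were chosen after the results were seen. The others were written before they were run. Those on depth, spread and ribosomal proteins, however, name strains or a pattern taken from the results.

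The number of changed loci at day 32 ran from 1 in Wood_21 and 3 in Desert_40 to 1770 in Grass_32. Lower depth as the whole cause is argued against, since the Pine_43 libraries thinned to the totals of the Desert_40 libraries gave a mean of 1382 changed loci over 5 draws. The common dispersion of Desert_40 was 1 times the median of the 9 strains, so no wider spread was seen by that measure. Being 1 value over all libraries, it cannot show single libraries far from their group. The day 1 libraries of Desert_40 had mean correlations with their own day of 0.26, 0.50 and 0.45, so spread stays open. Neither test covers Wood_21, whose dispersion was 6.42 times the median. The count in Desert_40 was 229 with libraries under 100000 counts left out and 196 without day 1 replicate 1, so single libraries may hold its count down. A difference between the strains stays open as an untested biological explanation.

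Ribosomal protein genes stood at −1.69 log2 (SD 1.25, n = 9) against all loci at day 32. Against the loci nearest in length the mean shift was −1.498 (SD 1.17), and against those nearest in mean abundance over all libraries of the strain −1.42 (SD 1.13). Neither length nor this mean abundance thus accounts for the whole mean shift. The mean abundance includes days 1 and 32, so a fall lowers it. Abundance at day 0 was not matched and stays open. Against loci of like length and of like abundance, however, Wood_52 went from −0.93 to 0.09 and −0.43, and Salt_16 from −0.44 to −0.07 and −0.03, so both stay open in these strains. Lower transcription and faster decay of these transcripts after day 0 could each give such a shift, and neither was tested. Whether drying or the loss of medium lay behind it cannot be told apart in this design. The hypothesis was tested on the same libraries that showed the pattern.

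Between day 1 and day 32 edgeR called 317 loci in Desert_35, 19 in Wood_52 and 0 in the other 7 strains. In Desert_35 a shallow day 1 library or the scaling as the whole cause of the number of calls is argued against, with 751 calls without day 1 replicate 1 and 334 with RLE size factors. The scaling did move the balance of higher and lower loci, as given above. The number of calls was also not stable, with 18 with length offsets, 69 by DESeq2 and 38 without day 32 replicate 3. Every exchange of 1 day 1 library with 1 day 32 library was run in the 9 strains, 9 exchanges per strain. In Grass_32 the exchange of day 1 replicate 2 with day 32 replicate 1 gave 850 calls in place of 0 and was the only best exchange after which the groups stood apart, so a mix-up of these libraries may be worth checking, as a hypothesis found by taking the best of 9. This exchange puts replicate 2 of both days in 1 group, and these libraries also deviated from their groups together (r = 0.574). A mix-up thus cannot be told apart from a pairing by replicate number. In Pine_43 the best exchange gave 956 calls but left the groups overlapping, and a library unlike its group stays as possible as an exchange. The same holds in Desert_35, where the exchange of replicate 1 of both days gave 569 calls in place of 317 and left the groups overlapping. Its day 1 replicate 1 had a mean correlation of 0.391 with its own day and 0.633 with day 32.

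Among 25 groups of strain values tested for a value far from the others, 1 had one: the nucleotide synthesis list in Wood_21 at day 32 against day 1, at 1.76. Chance gives such a value in about 1 in 20 groups. The clade test at day 32 gave limma adjusted p-values of 0.000202 for rplO, 0.000787 for rpsB, 0.00312 for rpsS, 0.0100 for dnaK, 0.0146 for msrB and 0.0175 for qcrB. The number of shared genes that differed between clades at day 32 was 14. Of 100 partitions of the strains 2 gave as many, the real one included, and the highest other gave 35, although none of these genes passed its own exact permutation test, in which a gene alone could not pass. At day 1 and at day 32 against day 1 the real clades gave 0 genes, all 100 partitions gave as many, and the highest others gave 6 and 0. The interaction of strain and time was found for 139 genes, and 1 of 50 draws, the real one, reached that count when time was shuffled within strains, with 31 the highest other. The shuffle also removes the change that the strains share. It therefore cannot tell whether 139 genes exceed what chance gives beside a common response. The tmRNA, which no comparison used, took a median of 56.4% of the reads.

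For the counts within strains, 6 libraries make 10 splits, too few for a share under 0.05. At day 1 against day 0 the real count and the highest of the other splits were 93 and 0 in MMLR14_002, 1078 and 0 in Salt_16, 1 and 0 in Wood_21, 1472 and 0 in Grass_32, 1815 and 0 in Pine_43, 711 and 0 in Wood_52, 264 and 6 in Desert_3, and 101 and 64 in Desert_35. Desert_40 had 0 in all 10 splits. At day 32 against day 0 they were 115 and 1 in MMLR14_002, 942 and 0 in Salt_16, 1770 and 0 in Grass_32, 1566 and 0 in Pine_43, 1025 and 0 in Wood_52, 372 and 0 in Desert_3, 1124 and 398 in Desert_35 and 3 and 0 in Desert_40. In Wood_21 the real count was 1, 7 splits gave as many, and the highest other was 29. At day 32 against day 1 they were 19 and 2 in Wood_52. In Desert_35 they were 317 and 569, with 2 splits as large. The real count was 0 in the other 7 strains, so all 10 splits gave as many, and the highest others were 0 in MMLR14_002 and Wood_21, 79 in Salt_16, 850 in Grass_32, 956 in Pine_43, 4 in Desert_3 and 44 in Desert_40. The high counts of other splits in Grass_32, Pine_43, Salt_16, Desert_40 and Desert_35 point to a structure of these libraries that their days do not follow.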

How the results depend on the processing

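Length offsets, the libraries left out of the deposited table, genes in at least 6 strains, exact tests per gene, groups at 0 at their bound and some fits without a strain were chosen after seeing the data. Of 2162 alternative values over 146 results, 1872 gave the same call or a count within 1.5 times, 177 counts or shares moved further, 94 calls ended, 19 were gained and 0 reversed direction. The 641 values that are counts or shares could not reverse by the way they were labelled. The other 1521 followed genes past the threshold and lists with an unadjusted p under 0.05 in the exact sign-flip test. Such a choice leaves little room for a reversal, and gains outside it are not counted. Where a value moved, the cause was not tested, except where fewer or more genes or libraries entered by construction. In simulations at each strain's depth and dispersion no 8-fold change was recovered in Wood_21 and 46.9% were in MMLR14_002. Their dispersions were 6.42 and 1.76 times the median of the strains, so these shares do not separate depth from spread.

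DESeq2 gave 161 and 180 changed loci in MMLR14_002 at days 1 and 32, 15 in Wood_21 at day 1, 284 in Desert_35 at day 1, and 29 and 69 in Desert_40 at days 1 and 32. At day 32 against day 1 it gave 69 in Wood_52, 69 in Desert_35 and 1 in Desert_40. Its fold changes gave 11 clade genes at day 1 and 22 at day 32. RLE size factors gave 0 in Wood_21 at both days, 237 in Desert_35 at day 1, 50 in Wood_52 at day 32 against day 1 and 23 clade genes at day 32. Without a filter on low counts Wood_21 had 0 at both days and Desert_40 had 32 and 28, and the shared genes with a common change were 104 at day 1 and 111 at day 32, with 1 clade gene at day 32. With structural RNA kept Wood_21 had 0 at both days. Length offsets gave 1 in MMLR14_002, 2 in Wood_21, 33 in Wood_52 and 18 in Desert_35 at day 32 against day 1, 0 in Wood_21 at both days and 0 in Desert_35 at day 1. They gave 0 clade genes at day 32, 6 common genes at day 32 against day 1 and 0 lists there, as did the list mean and members with a single copy.

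With libraries under 100000 counts left out the counts were 2 and 1 in MMLR14_002 at days 1 and 32, 930 in Grass_32 at day 1, 1 and 229 in Desert_40 at days 1 and 32, and, at day 32 against day 1, 32 in Wood_52, 835 in Desert_35 and 8 in Desert_40. Without the libraries left out of the deposited table they were 31 and 16 in MMLR14_002 and 0 and 0 in Wood_21. Common genes were 97 at day 1 and 107 at day 32 without Wood_21, 59 at day 1 without Wood_52, and 216 and 259 among genes in at least 6 strains. Clade genes at day 1 were 1 without Pine_43 and 21 without Wood_52. At day 32 they were 8 without MMLR14_002, 6 without Salt_16, 0 without Wood_21, 4 without Grass_32, 41 without Wood_52, 6 without Desert_35, 0 among genes in at least 6 strains and 0 by the exact permutation, and at day 32 against day 1 there was 1 without Wood_21.

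The replicate numbers did not pair the samples throughout: over 81 pairs the correlation of deviations ran from −0.473 to 0.574, 19 pairs were over 0.1, 28 were best with their own number, and 0 of 9 strains had every pair over 0.1. Salt_16 was an exception in part, with 8 of its 9 pairs best with their own number. Its day 1 and day 32 libraries correlated at 0.436, 0.166 and 0.400 for replicates 1, 2 and 3, so a pairing there stays open. For the same days replicates 1, 2 and 3 correlated at 0.248, 0.574 and −0.183 in Grass_32 and at −0.473, 0.561 and 0.283 in Pine_43. A pairing of replicate 2 in these strains stays open as well. With the replicate number as a block the counts were 53 and 61 in MMLR14_002 at days 1 and 32, 0 and 0 in Wood_21, 162 and 237 in Desert_3, 4 and 683 in Desert_35, and, at day 32 against day 1, 41 in Wood_52 and 146 in Desert_35. In Desert_35 at day 1 the block ended the call of rplN (edgeR, adjusted p = 0.078). The block gave 4 clade genes at day 32 and 62 interaction genes. Of the lists, the block ended the call of glycolysis and the pentose phosphate pathway at day 32 (exact test, adjusted p = 0.0927) and gave calls for ATP synthase at day 1 and nucleotide synthesis at day 32 (adjusted p = 0.0453 each in the exact test).

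With each replicate left out in turn, changed loci at day 1 ran from 31 to 136 in MMLR14_002, 665 to 1554 in Salt_16, 0 to 59 in Wood_21, 930 to 1508 in Grass_32, 1495 to 2494 in Pine_43, 358 to 844 in Wood_52, 113 to 423 in Desert_3, 6 to 179 in Desert_35 and 0 to 13 in Desert_40. At day 32 they ran from 16 to 156, 458 to 1404, 0 to 56, 1107 to 1832, 1120 to 2279, 907 to 1230, 203 to 535, 478 to 1415 and 0 to 196 in the same order of strains. At day 32 against day 1 they ran from 0 to 0, 0 to 46, 0 to 80, 0 to 0, 0 to 1205, 1 to 173, 0 to 1, 38 to 751 and 0 to 59. Common genes ran from 22 to 62 at day 1, 28 to 51 at day 32 and 0 to 9 at day 32 against day 1. Clade genes ran from 0 to 12 at day 32 and were 0 elsewhere, and interaction genes from 30 to 59. Lists ran from 0 to 8 at day 1, 0 to 9 at day 32 and 0 to 1 at day 32 against day 1, with 0 for clades. Shares of variance ran from 35.3% to 42.9% for strain, 7.79% to 10.0% for time and 16.97% to 22.1% for the interaction.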

Other observations

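The tests of the tmRNA share and the values of genes with a strain group at 0 were chosen after the results were seen, and the clade correlations before. For several further genes 1 strain, or 2 for gmhA, had no read in a group, and their means are given with such strains at their bound. A bound lowers the mean but can also narrow the spread over strains, so the p-values at the bound need not be conservative. The riboflavin synthesis gene ribH stood at 2.67 log2 at day 1 (limma, adjusted p = 0.000125) and 2.63 at day 32 (adjusted p = 1.23e-05). The GTP cyclohydrolase gene folE stood at 2.58 and 2.60 (limma, adjusted p = 0.000515 and 6.62e-05), and gmhA at 2.73 and 2.86 (adjusted p = 0.000957 and 0.000261). The gene treZ, of the trehalose list described above, stood at 1.30 and 1.34 (limma, adjusted p = 0.0138 and 0.00504), but missed the threshold with the fitted values (adjusted p = 0.131 and 0.0758).

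Counted in each strain apart, flagella and chemotaxis loci were higher in 25 and lower in 3 of 87 at day 1 (27 and 3 adjusted over the list alone), and 24 and 4 at day 32 (26 and 6), while the list shift of 0.41 (SD 0.609, n = 7) at day 32 missed the threshold (exact sign-flip test, adjusted p = 0.320). Iron uptake loci were higher in 14 and lower in 5 of 50 at day 32 (17 and 5 adjusted over the list alone), with a shift of 0.12 (SD 0.971, n = 8, exact test, adjusted p = 0.824). Sugar ABC transport and glycan breakdown had 30 higher and 41 lower of 231 at day 32 (27 and 39 adjusted over the list alone), with a shift of −0.58 (SD 0.937, n = 9, exact test, adjusted p = 0.244, but 0.0453 from DESeq2 fold changes). Oxidative stress defence had 38 higher and 29 lower of 214 (39 and 30 adjusted over the list alone), with a shift of 0.11 (SD 0.642, n = 9, exact test, adjusted p = 0.717).

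The remaining lists missed the threshold at both days in the exact sign-flip test, although amino acid synthesis passed at day 1 without replicate 1 of every group and RNA polymerase at day 32 with length offsets (adjusted p = 0.0425 each). At day 32 the shifts were −0.60 for the TCA and glyoxylate cycle, −0.50 for RNA polymerase and transcription factors, −0.44 for stringent response and ribosome hibernation, −0.30 for RNA degradation, −0.28 for glycogen metabolism, −0.23 for fatty acid synthesis, −0.22 for peptide and amino acid uptake, −0.13 for carotenoid and isoprenoid synthesis, −0.10 for amino acid synthesis, 0.19 for DNA repair and SOS, 0.31 for sigma and anti-sigma factors and 0.47 for fatty acid oxidation.

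A hypothesis was that strains of 1 clade respond more alike. Over the 64 shared genes the mean correlation of fold changes across genes, which are not independent replicates, was 0.630 within and 0.477 between clades at day 1, a difference that 0.0107 of the 280 partitions of the strains matched (exact permutation). At day 32 it was 0.662 and 0.542 (exact permutation, p = 0.0143). Without Wood_21, over 209 genes, p was 0.0357 and 0.0143 in the exact permutation. Strains of 1 clade may thus respond more alike, although no single gene passed its own exact test, which a gene alone could not pass.

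Another hypothesis was that the tmRNA share changes with time on the slides. It differed by a mean of 3.66 percentage points at day 1 (SD 12.4, higher in 6 of 9 strains, exact sign-flip test, p = 0.375) and −1.33 at day 32 (SD 13.5, higher in 4 of 9 strains, exact p = 0.773), which leaves a change in either direction open.

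The authors' deposited table, which covers named genes only, had 818 genes with an adjusted p under 0.05 at day 1 and 1016 at day 32 in Grass_32, 794 and 755 in Pine_43, 540 and 475 in Salt_16, and 19 and 60 in Desert_40. In the authors' deposited table Desert_40 had 4 genes higher and 56 lower at day 32.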
